A study of Homo sapiens with 12 samples.

How the data were processed

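RNA was measured by bulk sequencing of stranded mRNA libraries from 3 established human lung cancer cell lines with a mutant EGFR gene: PC9, HCC827 and HCC4006. The 12 libraries fall into 6 groups of 2, given by cell line and treatment. Control cells received the solvent DMSO for 24 hours. Cells that the labels call dormant received 100 nM osimertinib, an inhibitor of EGFR, with 30 nM trametinib, an inhibitor of the kinase MEK, for 2 weeks. Treatment therefore differs from control in duration as well as in drug, and the labels also give a larger culture dish for dormant cells, so these cannot be separated. The labels say that plates were set up in duplicate. Nothing says that the 2 plates of a group came from separately grown cultures, so every p-value measures only the spread between these samples.

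The deposited values are FPKM, fragments scaled to gene length and library size, computed by the authors and rounded to 0.01. The submitters' notes name STAR 2.5.1b, Cufflinks 2.2.1 and DESeq2 1.10.1 and the builds hg19 and GRCh37, without giving a role or an order. The table holds 57905 genes and 24 value columns, 2 for each library. The names of both columns of a library differ as those of the files of a read pair do, and the notes do not state what each column holds. Both were averaged and counted as 1 library. Genes are named by the symbols of that table. The 27 symbols that a spreadsheet had turned into dates were looked up by gene identifier in GENCODE v29, which also gave gene type, length and GC content. No gene position is given, because that annotation is on a later build than the authors' values.

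No counts are among the values analysed here, so the sequencing depth of each library is unknown and no counting interval can be given. The FPKM values of a library summed to between 793883 and 1159352. A relative depth was read from the spacing of FPKM values in U6 pseudogenes, short genes of near equal length. The step that most values matched at 1 or 2 times its size was taken to stand for a single read. By that measure the second HCC4006 dormant library had 38% of the depth of the first PC9 DMSO library, and the others had 67% to 104%. The step of that dormant library rested on 15 values, against 17 to 38 in the others.

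Values were analysed as log2(FPKM + 1) with no further scaling. Adding 1 makes the fold change of genes with low FPKM smaller than the ratio of their values. Genes with at least 1 FPKM in at least 2 of the 12 libraries were tested, which left 14699. A linear model with 1 coefficient per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 6 residual and 3.8 prior degrees of freedom. Each gene has 1 estimate of its spread, shared by all 6 groups, so the SE given for a line is not that line's own. The contrasts were dormant minus DMSO within each line, the mean of these 3 differences with equal weight, and a moderated F test of whether the difference varied between lines. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the figures.

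Before the data were examined, 36 gene lists were fixed, together with the tests, the alternatives to be tried and the rule for naming genes. Each list was tested with limma's camera against all other tested genes, with an inter-gene correlation preset to 0.01 and again with one estimated from the data, adjusted over the 36 lists. Members of a list were also adjusted over the list alone. The rule named the 10 genes with the largest and the 10 with the smallest mean difference among those called in the mean and in every line with 1 sign. It named the 5 largest and 5 smallest called differences per line where both dormant libraries lay on 1 side of both DMSO libraries. It named the 8 genes with the widest range of differences among those called different between lines and called with opposite signs in a pair of lines. Up to 4 members of each list with the largest mean difference among those called were added, with 23 single genes. A few genes that met this rule are not reported here, and all fits, totals and lists include them. BBC3 and SPRY4, both among these single genes, were below the filter and were not tested. UHRF1, TXNIP, BOP1, PECAM1 and 12 histone genes of the lists were not found under their symbol and are not analysed here.

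The procedure was tested on simulated data in which 100 genes were changed by 1 log2 unit and another 100 by 2, with the same spread in all libraries. In the mean over lines, 14% of genes changed by 1 log2 unit and 60% of those changed by 2 were called in the right direction. For single lines, 0% to 2% of the smaller changes and 0% to 14% of the larger were called. A gene that was not called in a line is therefore not shown to be unchanged there. Fewer genes were changed in the simulation than were called in the data, which makes the adjustment stricter, so the rates in the data may differ.

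The alternatives fixed at that point were other pseudocounts, filters, scalings, variance models and list tests, a fit of each line alone, line means as replicates, a block for the replicate number, and each library left out in turn. After the data were seen, 3 kinds of alternative were added: a fit without the second HCC4006 dormant and the second HCC827 DMSO library, the removal of trends on GC content and transcript length (known for 96.5% of tested genes), and either column of each library alone.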

Results

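Gene expression was compared between untreated and drug-treated lung cancer cells of 3 lines, PC9, HCC827 and HCC4006, with 2 libraries per line and treatment. Treated cells had received osimertinib with trametinib for 2 weeks and are called dormant in the labels. Controls had received DMSO for 24 hours. The study's title concerns the role of YAP, a partner of transcription factors, in the regulation of cell death genes in dormant cells. All values are FPKM as deposited, group values are mean ± SD of 2 libraries, and differences are dormant minus DMSO on the scale of log2(FPKM + 1), with their SE.

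Of the 12 libraries, 2 stood apart from their replicate. The second HCC4006 dormant library listed the glycolytic enzyme gene GAPDH at 6.7 FPKM, against 3755.3 to 19644.7 in the others. Mitochondrial tRNA made up 20% of its summed FPKM, against 0.51% to 2.66% elsewhere. It listed 1948 tested genes at 0, against 368 to 802. Across genes, which are not independent replicates, its values correlated with those of the first HCC4006 dormant library at a Pearson r of 0.654. Both HCC827 DMSO libraries correlated at 0.909, and the second of them listed the actin gene ACTB at 1842.5 FPKM, against 12726.2 in the first. The other replicate pairs correlated at 0.979 to 0.991. Values without both of these libraries, called the doubted libraries here, are given beside each group of genes, a check chosen after the data were seen.

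**Figure D1:**
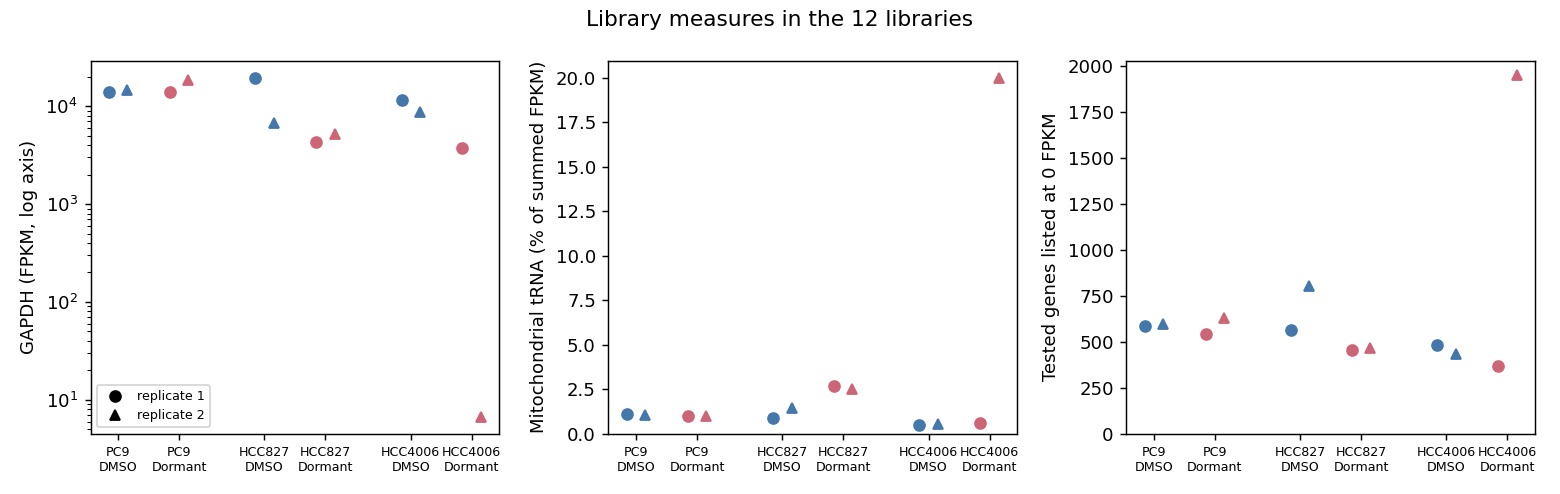
GAPDH in FPKM on a log axis, mitochondrial tRNA as a percentage of summed FPKM, and the number of tested genes listed at 0, each point being 1 of the 12 libraries (blue, DMSO; red, dormant). The second HCC4006 dormant library lies at 6.7 FPKM, 20% and 1948 genes.

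In the mean over the 3 lines, dormant cells had lower expression of cell division genes and higher expression of genes of autophagy, matrix and growth arrest, by list tests of which that of mitosis alone was also called with a correlation estimated from the data. NPPB, which encodes a natriuretic peptide, rose by 4.82 ± 0.28 (adjusted p = 8.21e-05). It was listed at 0 in each of the PC9 DMSO libraries and at 30.8 ± 2.46 FPKM in dormant PC9, and went from 0.48 ± 0.3 to 39.7 ± 3.33 in HCC827 and from 0.338 ± 0.018 to 37.4 ± 24.6 in HCC4006. GABARAPL1, an autophagosome protein, rose by 4.15 ± 0.27 (adjusted p = 0.000117), from 5.84 ± 1.3 to 158 ± 9.49 FPKM in PC9. CCNB1, the cyclin of entry into mitosis, changed by -3.6 ± 0.35 (adjusted p = 0.000332), from 554 ± 56 to 15.1 ± 1.51 FPKM in HCC827. DUSP6, a phosphatase induced by ERK signalling, changed by -3.4 ± 0.41 (adjusted p = 0.000874). It went from 3.56 ± 0.035 FPKM in PC9 and from 8.04 ± 7.1 in HCC827 to being listed at 0 in each dormant library of both lines, and from 88.5 ± 14 to 2.25 ± 2.82 in HCC4006.

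In this mean 1599 genes rose and 669 fell, of 14699 tested, and 951 and 462 of them differed by at least 1 log2 unit. With both doubted libraries left out, 4415 rose and 1884 fell. Of the 12 libraries, 9 each moved the total of 2268 by over 1.5 times when left out, from 1025 without the first PC9 DMSO library to 7390 without the first HCC4006 dormant library. The share of called genes that rose was 70.5%, and it was 57.8% with median of ratios scaling, 49% with quantile normalization and 48.4% after removal of GC and length trends. The median difference of all tested genes was 0.22, and these scalings and that removal brought it to 0.11, 0.03 and 0.02, so how far up-regulation outweighed down-regulation depends on the scaling. The mean was tested against the spread between libraries of a line. With the 3 lines themselves as replicates, 2 genes were called, NPPB and PSG5, both named in this comparison by the fixed rule. Of the 131 named genes called in the mean, 93 kept their call whichever of the 12 libraries was left out. The other 38 lost it in at least 1 case, among them CDC45, NCL, NOP16, NOP56, RPL27, RPS2, RPL35, NEU1, MX1, TAGLN, WWC1, AMOTL1, TEAD3, BCL2L11, BCL2A1, TP53INP1, BTG2, PHLDA3 and AEN, which are named below.

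The genes called in every line with 1 sign numbered 33 higher and 12 lower, against 0.401 and 0.0223 if the lines' lists were independent. The lines share their estimate of the spread, so their lists are not fully independent and these numbers may be too low. Leaving out 1 library gave 5 to 218 higher and 1 to 133 lower, the replicate block 6 and 1, a fit of each line alone 0 and 0, and the fit without both doubted libraries 409 and 216. The highest after NPPB were PSG5, a pregnancy-specific glycoprotein (4.56 ± 0.26), FILIP1L (4.17 ± 0.26), GABARAPL1 and the histone HIST1H2AC (4.13 ± 0.34). They were followed by the lipase ABHD4 (3.81 ± 0.33), the xenobiotic-metabolising CYP1A1 (3.8 ± 0.29), the adhesion scaffold NEDD9 (3.66 ± 0.26), PDZK1IP1 (3.47 ± 0.4) and the matrix protein MATN2 (3.36 ± 0.33). Those that fell furthest included G0S2, an inhibitor of fat breakdown (-4.13 ± 0.3), the histone HIST1H4C (-3.19 ± 0.37), the CDK partner CKS1B (-3.04 ± 0.29) and the ecto-nucleotidase NT5E (-2.96 ± 0.28). HMGA1 (-2.86 ± 0.22), MYEOV (-2.82 ± 0.19), the metallothionein MT1A (-2.76 ± 0.27), GPAT3 (-2.54 ± 0.27) and the histone variant H2AFZ (-2.53 ± 0.27) were lower too. PSG5 and both HIST genes have close copies in the genome, so their reads may be shared with these.

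**Figure D2:**
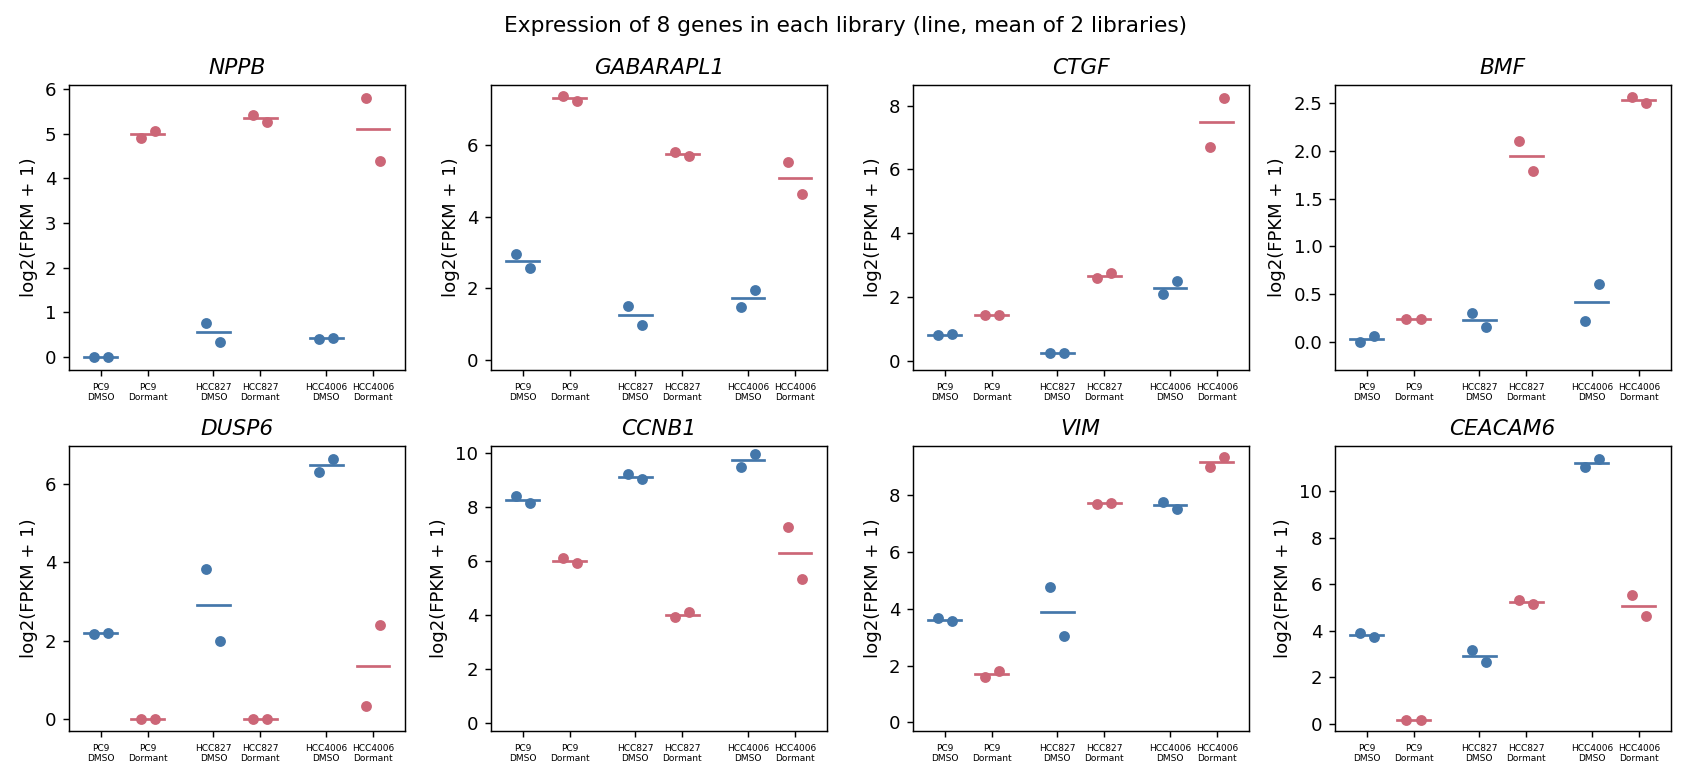
Expression as log2(FPKM + 1) of 8 genes in each library (points; blue, DMSO; red, dormant) with the mean of 2 libraries (line). NPPB rose by 4.82 and CCNB1 fell by 3.6 in the mean over lines, whereas CEACAM6 differed in direction between lines.

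Genes of cell division fell together. Of 25 tested mitosis genes, 24 fell and CENPE was not called, both over all genes and adjusted over the list alone, with a median difference of -2.48 (camera adjusted p = 2.49e-26). The largest changes were in UBE2C (-4.28 ± 0.55), CDC20 (-4.1 ± 0.76), CCNB1 and the kinase AURKB (-3.54 ± 0.43). MKI67, the proliferation marker, changed by -1.71 ± 0.23. Of 23 genes of S phase and DNA replication, 16 fell (20 adjusted over the list alone), among them the nucleotide reductase subunit RRM2 (-4.36 ± 0.61), GINS2 (-3.05 ± 0.37), CDC6 (-2.31 ± 0.33) and CDC45 (-2.11 ± 0.51). The list's adjusted p was 1.91e-16. It was not called with an estimated correlation (adjusted p = 0.113 with an estimated correlation), whereas mitosis was (adjusted p = 0.0405 with an estimated correlation), and mitosis was the 1 list of 36 of which that holds in the mean. This call was lost without both doubted libraries (adjusted p = 0.268 with an estimated correlation). Of 15 CDK inhibitors and quiescence genes, 6 rose (8 adjusted over the list alone), with an adjusted p of 0.000198 (adjusted p = 0.174 with an estimated correlation). HBP1 (2.29 ± 0.26), the CDK4 and CDK6 inhibitor CDKN2B (2.23 ± 0.21), YPEL3 (1.21 ± 0.18) and RBL2 (1.01 ± 0.19) led them, while CDKN1A was not called (0.38 ± 0.26, adjusted p = 0.341). The difference of CDKN2B varied between lines (F test adjusted p = 0.0141), so its mean does not describe each line. When both doubted libraries were left out, 25 mitosis and 22 S phase genes fell and 9 quiescence genes rose.

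Genes induced by the MAPK pathway, which trametinib blocks, were lower in dormant cells. Of 18 tested, 10 fell and none rose (12 and none adjusted over the list alone; 16 fell and 1 rose without both doubted libraries), with an adjusted p of 2.12e-09 (adjusted p = 0.113 with an estimated correlation). Beside DUSP6 these included PHLDA1 (-2.7 ± 0.28), the AP-1 member FOSL1 (-2.64 ± 0.34) and cyclin D1, CCND1 (-2.41 ± 0.37). ETV5, a transcription factor downstream of ERK, changed by -1.79 ± 0.2 (adjusted p = 0.00054) and was called in each line, though of the 12 cases of a library left out, 6 ended the call in PC9, 3 that in HCC827 and 2 that in HCC4006. MYC was not called (-0.32 ± 0.29, adjusted p = 0.467), nor was EGFR (-0.28 ± 0.33, adjusted p = 0.579). MYC was called with both doubted libraries left out (-0.57, adjusted p = 0.0165), and EGFR was not (adjusted p = 0.0572).

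Growth and energy genes were lower as lists in the mean over lines, with few single genes called. Of 29 ribosome biogenesis genes, 7 fell (8 adjusted over the list alone; 15 without both doubted libraries), among them NCL (-1.69 ± 0.36), NOP16 (-1.57 ± 0.42), NOP56 (-1.49 ± 0.37) and NPM1 (-1.47 ± 0.26), with an adjusted p of 1.63e-08 (adjusted p = 0.113 with an estimated correlation). Of 35 cytosolic ribosomal protein genes, RPL27 (-1.06 ± 0.32), RPS2 (-0.99 ± 0.26) and RPL35 (-0.98 ± 0.28) fell and limma called 0 adjusted over the list alone, with 9 lower at an unadjusted p under 0.05. The mean difference of these genes was -1.45 in HCC4006, against -0.27 in PC9 and -0.32 in HCC827. That list's adjusted p was 7.68e-08 (adjusted p = 0.396 with an estimated correlation), and without both doubted libraries 16 fell and 1 rose. Of 20 glycolysis genes, LDHA alone fell (-2.68 ± 0.52), over all genes and over the list alone, with a list adjusted p of 0.00125 (adjusted p = 0.486 with an estimated correlation). The glycolysis list was called in HCC4006 alone (mean difference -1.96, adjusted p = 8.57e-05; adjusted p = 0.426 with an estimated correlation), which holds the doubted library with little GAPDH, and not in PC9 (-0.27, adjusted p = 0.387) or HCC827 (-0.15, adjusted p = 0.185). With both doubted libraries left out, 14 glycolysis genes fell and 1 rose in the mean, and the list was called downwards in PC9 (adjusted p = 0.0479), HCC827 (adjusted p = 5.2e-09) and HCC4006 (adjusted p = 1.01e-09), though in none of them with an estimated correlation (lowest adjusted p = 0.171 with an estimated correlation). Of 27 nuclear-encoded oxidative phosphorylation genes, cytochrome c, CYCS, alone fell (-1.84 ± 0.33), by both adjustments, with a list adjusted p of 0.0353 (adjusted p = 0.396 with an estimated correlation). By line this list too was called in HCC4006 alone (adjusted p = 0.0162; adjusted p = 0.382 with an estimated correlation), a call lost in 1 of the 12 cases of a library left out. Of 13 mitochondrially encoded genes, limma called 0 by either adjustment and 2 were lower at an unadjusted p under 0.05, with a list adjusted p of 0.0273 (adjusted p = 0.43 with an estimated correlation). This mean joins opposite directions, since the list was lower in PC9 and higher in HCC827, where 12 of the 13 had a positive difference (adjusted p = 0.0291; adjusted p = 0.449 with an estimated correlation), a call lost in 2 of the 12 cases of a library left out (adjusted p up to 0.312). Fry, a rotation test of each list by itself, tests against a difference of 0. The upward median of all tested genes (0.22) therefore weighs against lower lists there. With fry, the calls of the ribosomal protein (adjusted p = 0.0923), glycolysis (adjusted p = 0.312), oxidative phosphorylation (adjusted p = 0.273) and mitochondrially encoded lists (adjusted p = 0.175) were lost. The calls of the last 2 also ended under quantile normalization, under trend removal and with a stricter filter, that of oxidative phosphorylation with equal column sums and that of mitochondrially encoded genes with line means. They reached an adjusted p of 0.0618 and 0.199 with a library left out, which ended them in 4 and 5 of 12 cases. Without both doubted libraries 3 oxidative phosphorylation genes rose and 5 fell, and 5 mitochondrially encoded genes fell.

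Target genes of YAP and its DNA-binding partners, the TEAD factors, were mostly higher in the mean. Of 21 tested, 12 rose and 2 fell (15 and 2 adjusted over the list alone, and also without both doubted libraries), with an adjusted p of 0.0008 (adjusted p = 0.396 with an estimated correlation). By line, the list was called upwards in HCC827 (7 rose and 2 fell, adjusted p = 0.000795; adjusted p = 0.449 with an estimated correlation) and HCC4006 (7 rose and 1 fell, adjusted p = 0.0016; adjusted p = 0.426 with an estimated correlation), and not in PC9 (1 rose and 1 fell, adjusted p = 0.0892). The secreted proteins CCDC80 (3.9 ± 0.36) and IGFBP3 (3.87 ± 0.54), ANKRD1 (3.0 ± 0.36), CTGF (2.74 ± 0.29, adjusted p = 0.000445) and CYR61 (1.58 ± 0.25, adjusted p = 0.00304) rose. NT5E and F3, the coagulation tissue factor, fell. CTGF went from 0.76 ± 0.028 to 1.7 ± 0.0106 FPKM in PC9, where it was not called (0.62 ± 0.5), from 0.18 in both libraries to 5.36 ± 0.559 in HCC827 and from 3.94 ± 0.94 to 203 ± 140 in HCC4006. Its difference varied between lines (adjusted p = 0.0281). Among 19 genes of the Hippo pathway and the TEAD factors, WWC1 (1.25 ± 0.3), AMOTL1 (0.8 ± 0.21) and TEAD3 (0.71 ± 0.21) rose by both adjustments. The list was not called (adjusted p = 0.286), though it was without a filter on low values (adjusted p = 0.0429) and with fry (adjusted p = 0.0239). Without that filter a list is compared with 40839 genes of median difference 0.03, against 0.22 with it. This can favour upward calls, which went from 9 lists to 14, with 8 downward in both fits. When both doubted libraries were left out, 8 of its genes rose and 3 fell. YAP1 itself was not called (0.37 ± 0.49, adjusted p = 0.629), with 12.6 ± 15.8 FPKM in dormant HCC4006 and -0.05 in the mean without both doubted libraries. It was called, at 0.93, without the first HCC4006 dormant library, but that fit leaves dormant HCC4006 to the doubted library alone. WWTR1, the paralog of YAP1, gave -0.89 ± 0.41 (adjusted p = 0.165), TEAD1 0.89 ± 0.34 (adjusted p = 0.106) and TEAD4 -0.39 ± 0.32 (adjusted p = 0.421). In fits that leave a lone library in dormant HCC4006, and so decide little, 2 of these were called. They were WWTR1 without the second library and TEAD1 without either. Both were called as well without both doubted libraries, WWTR1 with adjusted p = 0.00217 and TEAD1 with adjusted p = 0.043, and so was TEAD4 (-0.78, adjusted p = 0.00725).

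Of 11 tested pro-apoptotic genes of the BCL2 family, 2 rose and none fell (4 and none adjusted over the list alone). The list was not called (adjusted p = 0.338), though it was without a filter on low values (adjusted p = 0.0254), which can favour upward calls as for the Hippo list. BMF, an activator of cell death, rose by 1.35 ± 0.15 (adjusted p = 0.000534). It went from 0.17 ± 0.085 to 2.88 ± 0.594 FPKM in HCC827 and from 0.342 ± 0.26 to 4.79 ± 0.187 in HCC4006, both called, and from 0.02 ± 0.028 to 0.175 in both libraries of PC9, not called. The HCC827 call was lost in 1 case of a library left out (adjusted p = 0.0778), under trend removal (adjusted p = 0.0971) and with each line fitted alone (adjusted p = 0.0581), and the HCC4006 call with array quality weights (adjusted p = 0.248) and with each line fitted alone (adjusted p = 0.604). The test of a difference between lines missed the threshold (adjusted p = 0.052). BCL2L11, which encodes the death activator BIM, rose by 0.7 ± 0.2 (adjusted p = 0.0396), a call lost in 9 of the 12 cases of a library left out (adjusted p up to 0.133). BBC3, listed at 0.0225 ± 0.018 FPKM in PC9 DMSO and at 1.03 ± 1.46 in dormant HCC4006, was below the filter. Of 9 anti-apoptotic genes, BCL2A1 fell (-0.92 ± 0.27). It was called in HCC827, where it went from 32.5 ± 25 to 2.92 ± 0.0813 FPKM, and its mean in the other groups lay between 0 and 0.085. Adjusted over the list alone 1 rose and 1 fell, and the list was not called (adjusted p = 0.59). With both doubted libraries left out, 5 pro-apoptotic genes rose and 1 fell, and 3 anti-apoptotic genes rose and 1 fell.

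Matrix and mesenchymal genes were higher in the mean, HCC827 and HCC4006 but not as lists in PC9. With an estimated correlation none of these lists was called in any line (lowest adjusted p = 0.121 with an estimated correlation), and in HCC4006 the mesenchymal, collagen and TGF-beta calls were each lost in 1 case of a library left out (adjusted p = 0.0516, 0.1 and 0.31). In PC9 the collagen and matrix list had a mean difference of -0.18 with 0 genes called higher and 2 lower (adjusted p = 0.594), the mesenchymal list a median of 0.01 (adjusted p = 0.421), and the TGF-beta list was not called (adjusted p = 0.062). Of 18 mesenchymal genes, 7 rose (13 rose and 1 fell adjusted over the list alone, and also without both doubted libraries), with an adjusted p of 0.0008 (adjusted p = 0.174 with an estimated correlation). Among these, the matrix proteins SPARC and FN1 rose by 2.53 ± 0.45 and 2.51 ± 0.26, and TAGLN by 2.46 ± 0.68. Among the single genes SNAI2 (0.86 ± 0.3, adjusted p = 0.0793), ZEB1 (0.31 ± 0.13, adjusted p = 0.119) and AXL (-1.42 ± 0.76, adjusted p = 0.224) were not called. Each was called without the first HCC4006 dormant library, a fit that leaves dormant HCC4006 to the doubted library alone. SNAI2 was called also without the first HCC827 DMSO library and without both doubted libraries. All of these fits leave a lone library in a group, so such calls decide little. Of 21 collagen and matrix genes, 10 rose and LAMA4 fell (13 and 2 adjusted over the list alone; 14 and 3 without both doubted libraries), with an adjusted p of 0.00326 (adjusted p = 0.174 with an estimated correlation). COL1A2 (2.5 ± 0.21), COL4A1 (1.77 ± 0.24), COL4A3 (1.66 ± 0.19) and COL4A5 (1.48 ± 0.25) led them. The F test called COL1A2 (adjusted p = 0.000465), COL4A1 (adjusted p = 0.0368) and COL4A3 (adjusted p = 0.0263) different between lines, so their means do not describe each line. Of 17 TGF-beta response genes, 8 rose (11 rose and 1 fell adjusted over the list alone; 10 and 1 without both doubted libraries), including ID3 (3.14 ± 0.33) and ID2 (2.44 ± 0.32), with an adjusted p of 0.00112 (adjusted p = 0.183 with an estimated correlation). Of 25 epithelial genes, the junction gene OCLN (1.91 ± 0.33) was among those that rose by both adjustments, CDH1 did not pass (0.89 ± 0.33, adjusted p = 0.0934), and the list was not called (adjusted p = 0.286). CDH1 was called without the second HCC4006 dormant library (adjusted p = 0.0166) and without both doubted libraries (adjusted p = 0.0109), and the list without the first HCC827 DMSO library (adjusted p = 0.0453). By line the epithelial list was called upwards in PC9 (adjusted p = 0.00514; adjusted p = 0.568 with an estimated correlation) and in HCC827 (adjusted p = 0.0113; adjusted p = 0.572 with an estimated correlation), and its mean difference in HCC4006 was -0.76, not called (adjusted p = 0.0685). The HCC827 call was lost without both doubted libraries (adjusted p = 0.0773) and in 1 case of a library left out (adjusted p = 0.262). Without both doubted libraries 11 epithelial genes rose and 2 fell.

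Lysosome and antigen presentation genes were higher in the mean as well, though in HCC4006 none of the 4 lists concerned was called. Of 29 lysosome and autophagy genes, 11 rose (13 adjusted over the list alone; 24 without both doubted libraries) and none fell, with an adjusted p of 0.000149 (adjusted p = 0.547 with an estimated correlation). In HCC4006 the list had a median of -0.12, with 14 genes positive and 15 negative (adjusted p = 0.788), and without both doubted libraries it was called upwards there too (adjusted p = 3.11e-06; adjusted p = 0.303 with an estimated correlation). Beside GABARAPL1 the genes that rose included WIPI1 (2.45 ± 0.35), NEU1 (1.79 ± 0.49) and TPP1 (1.71 ± 0.29). Of 28 interferon-stimulated genes, 7 rose (11 adjusted over the list alone; 19 rose and 1 fell without both doubted libraries), led by IFIT2 (1.85 ± 0.28), IFIT3 (1.84 ± 0.31), IFI6 (1.83 ± 0.25) and MX1 (1.5 ± 0.4), with an adjusted p of 0.00456 (adjusted p = 0.43 with an estimated correlation). Of 16 genes of MHC class I presentation, 5 rose (6 adjusted over the list alone; 12 without both doubted libraries), among them HLA-B (2.54 ± 0.39) and HLA-F (2.43 ± 0.34), with an adjusted p of 0.00456 (adjusted p = 0.466 with an estimated correlation). Of 11 genes of MHC class II presentation, 4 rose (6 adjusted over the list alone; 9 without both doubted libraries), led by HLA-DQA1 (1.21 ± 0.12) and HLA-DRB1 (1.15 ± 0.17), with an adjusted p of 0.0125 (adjusted p = 0.506 with an estimated correlation). Without the first HCC4006 dormant library the interferon (adjusted p = 0.103), class I (adjusted p = 0.103) and class II lists (adjusted p = 0.345) were not called, and the class II list was not called with line means (adjusted p = 0.0934). By line, the interferon list was called in HCC827 alone (adjusted p = 2.5e-05; adjusted p = 0.271 with an estimated correlation), with adjusted p = 0.117 in PC9 and 0.541 in HCC4006. The class II list was called in HCC827 alone (adjusted p = 0.00945; adjusted p = 0.502 with an estimated correlation), a call lost in 1 of the 12 cases of a library left out. The class I list was called in PC9 (adjusted p = 0.0114; adjusted p = 0.562 with an estimated correlation) and HCC827 (adjusted p = 0.00765; adjusted p = 0.502 with an estimated correlation). With both doubted libraries left out, the interferon (adjusted p = 0.011), class I (adjusted p = 1.05e-06) and class II lists (adjusted p = 0.00313) were called in HCC4006, though not with an estimated correlation (lowest adjusted p = 0.303 with an estimated correlation). The F test called HLA-DQA1 different between lines (adjusted p = 0.0035), so its mean does not describe each line. HLA genes vary between people and resemble each other, so reads of 1 HLA gene may be counted under another. Of 23 genes for secreted factors of senescent cells, 9 rose and 4 fell (10 and 4 adjusted over the list alone; 11 and 4 without both doubted libraries), the EGFR ligand AREG falling most (-2.69 ± 0.24), and the list was not called (adjusted p = 0.501), though it was with fry (adjusted p = 0.0264) and upwards in PC9 (adjusted p = 0.0247; adjusted p = 0.562 with an estimated correlation). Of 18 p53 targets, TP53INP1 (1.85 ± 0.53), BTG2 (0.9 ± 0.24) and PHLDA3 (0.72 ± 0.21) rose and AEN fell (-1.26 ± 0.36), with 3 and 2 adjusted over the list alone. That list was not called (adjusted p = 0.792), and 6 rose and 2 fell without both doubted libraries.

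**Figure D3:**
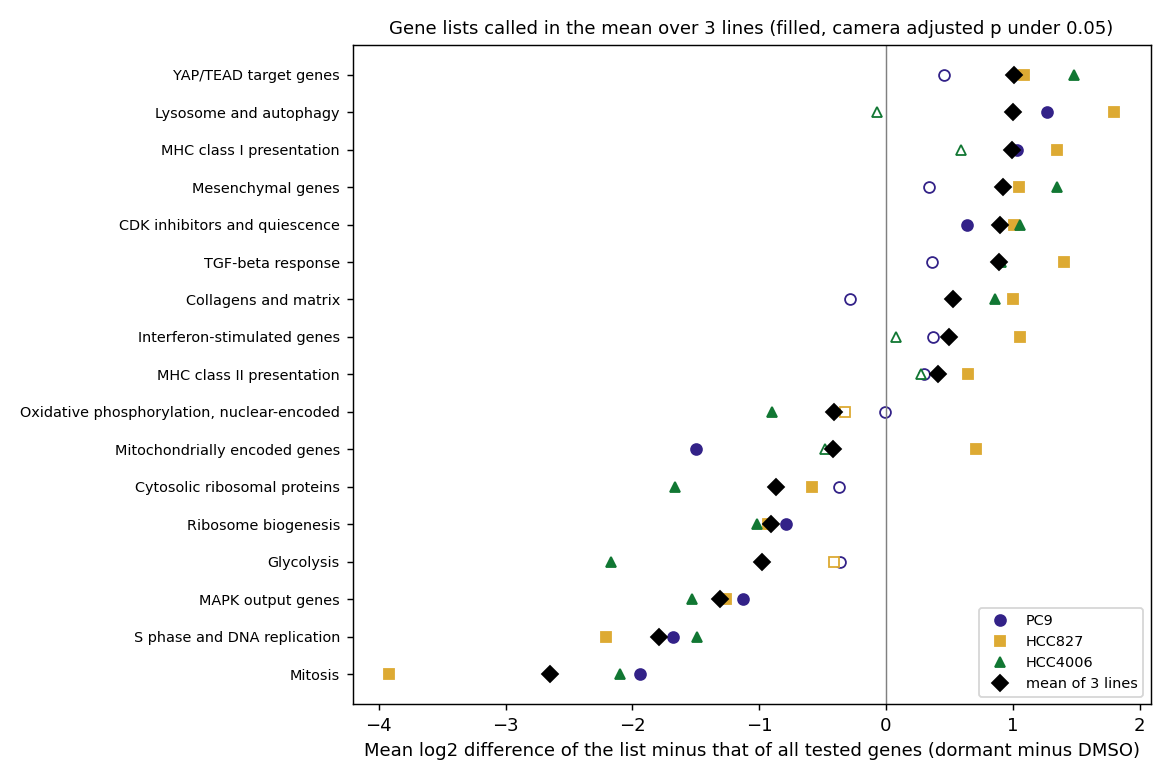
Mean log2 difference of each gene list called in the mean over 3 lines, less the mean over all tested genes (x axis), with 1 symbol per line and a diamond for the mean; filled symbols mark a camera adjusted p under 0.05 with the preset correlation. Of the 17 lists, 9 lie to the right and 8 to the left, and mitosis lies lowest.

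In PC9, dormant cells had far more MGP, an inhibitor of matrix calcification, and far less TGM2, a protein cross-linking enzyme. MGP went from 20 ± 2.3 to 2550 ± 235 FPKM (6.92 ± 0.56, adjusted p = 0.000165), and TGM2 from 152 ± 4.6 to 0.513 ± 0.421 (-6.69 ± 0.43, adjusted p = 7.28e-05). LY6G6C (6.09 ± 0.32), the linker histone HIST1H1C (5.74 ± 0.75), and the alkaline phosphatase ALPP (5.68 ± 0.41) also rose. TRBC2 (-4.87 ± 0.37) and TRBJ2-1 (-4.73 ± 0.58), segments of the T cell receptor beta locus, MYEOV (-4.44 ± 0.34) and the matrix protein TGFBI (-4.36 ± 0.57) fell. ALPP and the T cell receptor segments have close copies, which makes their assignment uncertain. Mitochondrially encoded genes had a median difference of -1.45, with 8 of 13 lower adjusted over the list alone and 0 called by limma over all genes, 8 being lower at an unadjusted p under 0.05. That list's adjusted p was 1.03e-07 (adjusted p = 0.176 with an estimated correlation). In all, 268 genes rose and 131 fell. The share that rose, 67.2%, was 56.2% under quantile normalization and 53% after trend removal. When both doubted libraries were left out, 1919 rose and 1272 fell. Of the 12 libraries, 10 each moved the total of 399 by over 1.5 times when left out, from 95 without the first PC9 DMSO library to 1638 without the first HCC4006 dormant library. The call of TGFBI was lost in 3 of these cases.

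In HCC827, among the genes named by the fixed rule and reported here, those that fell furthest were genes of the cell cycle. UBE2C, which marks mitotic proteins for destruction, went from 419 ± 180 to 3.16 ± 0.255 FPKM (-6.59 ± 0.95, adjusted p = 0.00577). RRM2 (-6.3 ± 1.06), PTTG1 (-5.7 ± 0.75), CDKN3 (-5.59 ± 0.56) and the mitotic kinase CDK1 (-5.57 ± 0.53) followed, and 19 of the 25 mitosis genes fell (24 adjusted over the list alone; 23 without both doubted libraries; adjusted p = 0.02 with an estimated correlation, and 0.279 with it and without both doubted libraries). The histone gene HIST3H2A went from 4.01 ± 2.9 to 1620 ± 66.6 FPKM (8.47 ± 1.25, adjusted p = 0.00618), with the reservation that histone genes share sequence. The keratin KRT17 (5.97 ± 1.02), the chemokine CCL2 (5.74 ± 0.47) and the endothelin EDN2 (5.71 ± 0.54) rose. VIM, which encodes vimentin, rose from 16.6 ± 13 to 208 ± 5.01 FPKM (3.81 ± 0.57, adjusted p = 0.00646), and SNAI2, a repressor of epithelial genes, from 3.57 ± 2.9 to 30.5 ± 0.308 (2.95 ± 0.52, adjusted p = 0.0125). In all, 450 genes rose and 211 fell. The share that rose, 68.1%, was 57.8% with median of ratios scaling, 52.2% under quantile normalization and 53.1% after trend removal. With both doubted libraries left out, 1634 rose and 965 fell. Of the 12 libraries, 9 each moved the total of 661 by over 1.5 times when left out, from 84 without the first HCC827 dormant library to 2974 without the first HCC4006 dormant library. The calls of UBE2C, RRM2, PTTG1, HIST3H2A, KRT17, VIM and SNAI2 were each lost in 1 to 3 of these cases, with an adjusted p up to 0.0785 for VIM and 0.125 for SNAI2.

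In HCC4006, among the genes named by the fixed rule and reported here, a collagen gene rose most and the epithelial adhesion gene CEACAM6 fell most. COL1A2, a chain of type I collagen, went from 0.905 ± 0.19 to 309 ± 83.5 FPKM (7.32 ± 0.36, adjusted p = 1.65e-05), and CEACAM6 from 2380 ± 430 to 34.6 ± 15.4 (-6.12 ± 0.46, adjusted p = 0.00023). NTM (7.05 ± 1.11), CCDC80 (6.13 ± 0.63), IGFBP7 (5.63 ± 0.96) and UBD (5.57 ± 0.63) rose, NTM with 1140 ± 1490 and IGFBP7 with 890 ± 1090 FPKM in dormant cells, so that the dormant libraries differed widely. The protease PRSS3 (-5.31 ± 0.57), DUSP6 (-5.12 ± 0.71), the calcium-binding S100A2 (-4.65 ± 0.48) and RRM2 (-4.53 ± 1.06) fell. ZEB1, a repressor of epithelial genes, rose from 0.095 ± 0.13 to 1.35 ± 0.428 FPKM (1.09 ± 0.22, adjusted p = 0.0213), but gave -0.05 after trend removal. In all, 718 genes rose and 174 fell. The share that rose, 80.5%, was 63.4% with median of ratios scaling, 54.8% under quantile normalization and 53.7% after trend removal. The calls in HCC4006 rest on a spread shared by all lines. With array quality weights 17 genes rose and 7 fell there, and with HCC4006 fitted alone limma called 0. Without both doubted libraries 2187 rose and 547 fell. Leaving out any of the 12 libraries moved the total of 892 by over 1.5 times, from 128 without the first HCC4006 DMSO library to 8607 without the first HCC4006 dormant library, which leaves the group to the library that stands apart. The calls of NTM, IGFBP7 and ZEB1 were lost in 2 of these cases and that of RRM2 in 10.

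Whether dormant cells of the lines differed from their controls in unlike ways was tested with the F test, which called 217 genes. VIM rose in HCC827, whereas its differences of -1.91 ± 0.57 in PC9 and 1.52 ± 0.57 in HCC4006 did not pass (adjusted p = 0.0177 between lines). MGP (adjusted p = 0.00223) and TGM2 (adjusted p = 0.00139), each called in PC9 and in no other line, varied between lines, as did COL1A2 (adjusted p = 0.000465), called in HCC4006. CEACAM6 fell in PC9 (-3.63 ± 0.46) and HCC4006 and rose in HCC827 (2.33 ± 0.46; adjusted p = 0.000844 between lines). Its relative CEACAM5 rose in HCC827 (1.62 ± 0.32) and fell in HCC4006 (-3.62 ± 0.32), as did the protease KLK10 (4.46 ± 0.56 and -2.41 ± 0.56), the receptor ADGRF1 (1.92 ± 0.43 and -1.79 ± 0.43) and GNRHR2P1, a pseudogene whose reads may come from its relatives (1.85 ± 0.43 and -2.41 ± 0.43). ADIRF (4.01 ± 0.87 and -3.5 ± 0.87) and the water channel AQP3 (2.48 ± 0.48 and -1.97 ± 0.48) rose in PC9 and fell in HCC4006. CALHM3 fell in PC9 (-1.27 ± 0.25) and rose in HCC827 (1.05 ± 0.25). Of these line calls, at least 1 was lost with a library left out for each of the 8 genes, in up to 11 of 12 cases for KLK10 in HCC4006. When both doubted libraries were left out, 1311 genes varied between lines. Of the 12 libraries, 11 each moved the total of 217 by over 1.5 times when left out, from 65 without the first PC9 DMSO library to 8050 without the first HCC4006 dormant library.

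Despite these differences, genes that rose or fell in 1 line tended to do so in another. PC9 and HCC827 shared 75 genes that rose, against 8.2 if independent, PC9 and HCC4006 shared 64 against 13.1, and HCC827 and HCC4006 shared 132 against 22. The genes that fell overlapped by 36, 30 and 46. The lines share 1 estimate of the spread per gene, which by itself can raise overlaps above the independent number. It would do so for opposite signs as well, yet genes called with opposite signs numbered 0 to 6 per comparison, against 3.17 to 10.3 if independent. Across all tested genes, which are not independent replicates, the differences of PC9 and HCC827 correlated at a Pearson r of 0.52, those of PC9 and HCC4006 at 0.23 and those of HCC827 and HCC4006 at 0.19. With both doubted libraries left out, these were 0.51, 0.49 and 0.59.

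**Figure D4:**
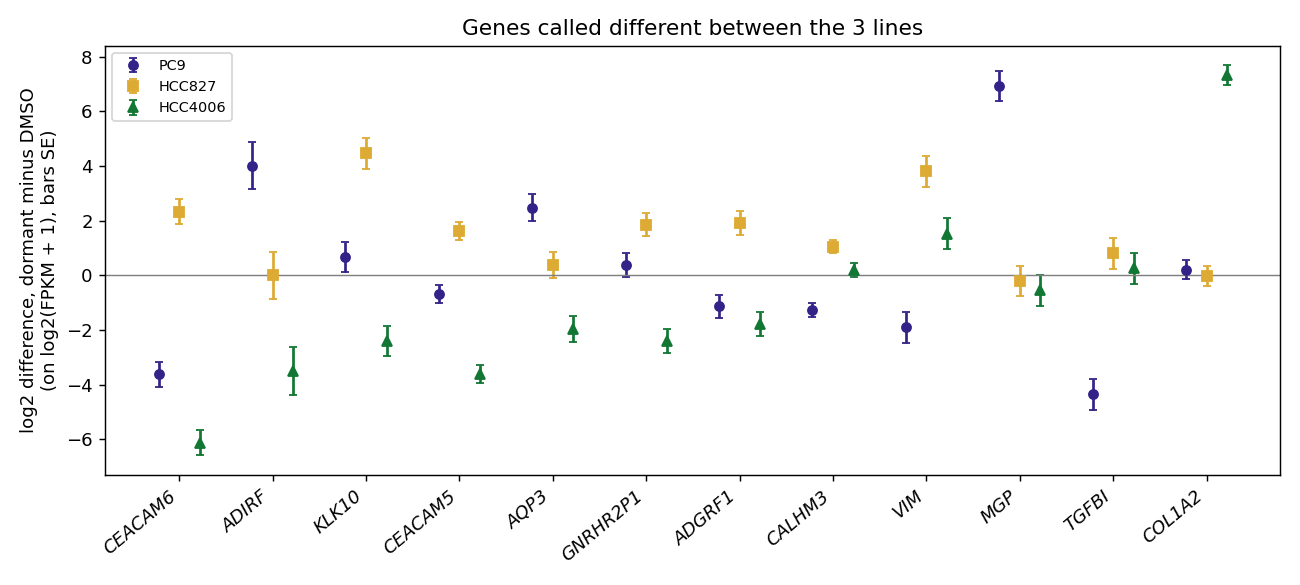
Log2 difference, dormant minus DMSO, with its SE (y axis) for 12 genes called different between lines, 1 symbol per line. CEACAM6 lies at 2.33 in HCC827 and at -6.12 in HCC4006, and MGP at 6.92 in PC9.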

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

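Both tests on the genes with opposite changes, the fit without the 2 doubted libraries, the removal of GC and length trends, the tests on small RNA genes of at least 10 FPKM and the H2A sum without HIST3H2A were chosen only after the results were seen. The other tests below were fixed before their result was known.

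What drew attention here was a difference between cell lines in the change from DMSO to dormant cells, by the moderated F test for genes and by camera for lists. The F test called 217 genes. Of the 168 genes looked at by name, low adjusted p-values were those of LY6G6C and COL1A2 (both 0.000465), CEACAM6 (0.000844), the secretoglobin SCGB3A1 (0.00108), and CEACAM5, TGM2 and the tubulin-binding TPPP3 (each 0.00139). MGP followed at 0.00223, ALPP at 0.00262, HLA-DQA1 at 0.0035, TRBC2 at 0.00353, CCL2 at 0.00599, KLK10 at 0.00676 and the collagen cross-linker LOX at 0.00965. Further ones were CDKN2B (0.0141), VIM (0.0177), GNRHR2P1 (0.0192), TGFBI (0.0206), COL4A3 (0.0263), CTGF, AQP3 and CALHM3 (each 0.0281), ADGRF1 (0.029), MYEOV (0.0321), COL4A1 (0.0368), ADIRF (0.0371), EGLN3 (0.0419) and TRBJ2-1 (0.0467). Reads of HLA-DQA1, ALPP, GNRHR2P1 and the T cell receptor segments are shared with close copies.

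For lists, 28 of 108 comparisons between a pair of lines were called, 38 without both doubted libraries and 26 in both fits. With an estimated correlation 0 were called by camera, the lowest adjusted p being 0.172. The mitochondrially encoded genes had a mean difference of 0.96 in HCC827 and -1.41 in PC9 (adjusted p = 2.98e-09 with the preset correlation; adjusted p = 0.172 with an estimated correlation). Mitosis genes stood at -3.67 in HCC827 and -1.85 in PC9 (adjusted p = 1.36e-12 and, with an estimated correlation, adjusted p = 0.172). Collagens stood at 1.26 in HCC827 and -0.18 in PC9 (adjusted p = 8.17e-06 and, with an estimated correlation, adjusted p = 0.172). Epithelial genes stood at -0.76 in HCC4006 and 0.98 in PC9 (adjusted p = 0.000378; adjusted p = 0.748 with an estimated correlation).

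The second HCC4006 dormant library differed from the first, with a Pearson r across genes of 0.654 and GAPDH at 6.7 FPKM. Its difference from the first fell with GC content (Spearman rho = -0.4) and was higher for long transcripts (rho = 0.22), but removing both trends from every library brought r to only 0.702, which argues against these trends as the whole cause. A wrong label for a library of another line is argued against as well: of genes specific to a line, the library held 0.72 of those of HCC4006 above 1 FPKM and 0.38 of those of HCC827, a gap of 0.33 that lies close to the bound of 0.3 set beforehand. A mixture with some HCC827 material remains open. Over 55 genes specific to HCC827, the rise from the first library to the second, as a share of the level in HCC827 libraries, had a median of 0.0086 (95% bootstrap interval 0 to 0.042), so a share over 1% is neither shown nor excluded, while for 88 genes specific to PC9 it was -0.0047. Degraded or scarce RNA was not tested and may also account for the low relative depth of 38% and for the 14 of 962 genes above 100 FPKM in the first library that lay under 1 in the second, and no biological explanation was tested, since both libraries share their group.

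A pattern to follow up is that 8 named genes, CEACAM6, ADIRF, KLK10, CEACAM5, AQP3, GNRHR2P1, ADGRF1 and CALHM3, rose in 1 line and fell in another. Genes of opposite sign were not in clear excess. The most, 6, rose in HCC827 and fell in HCC4006, against 5.33 if the lists were independent. Of the 8, all 8 again had opposite signs in a pair of lines once both doubted libraries were left out, so these directions do not depend on those libraries. Whether the calls depend on them cannot be decided by that fit. It leaves some groups with a lone library and called more genes in every comparison, so a call was unlikely to be lost there. With GC and length trends removed, 7 of the 8 were again called between lines with opposite signs. This argues against the trends for all but CALHM3, whose adjusted p between lines became 0.0902. In the planned fits the call between lines was kept by all 8 with each other scaling, robust variance estimation and array quality weights, by 7 with a pseudocount of 0.5, by the 7 that pass a filter of 5 FPKM, by 4 with no filter on low values, by 3 with a pseudocount of 0.1, by 0 with the replicate block, and by 3 to 8 with a library left out. A biological difference between the lines, which the design names, remains open and untested beyond these 3 lines, as does the sharing of reads between GNRHR2P1 and its relatives.

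Some histone genes were higher in dormant cells although cell division genes were lower. Summed over 14 H2A genes, FPKM went from 9.85 ± 0.601 to 273 ± 15 in PC9, from 37 ± 5.78 to 1820 ± 78.7 in HCC827 and from 7.75 ± 0.668 to 57.3 ± 2.76 in HCC4006. In HCC827 most of this was HIST3H2A, and the other 13 went from 32.9 ± 2.86 to 199 ± 12.1. By contrast, the sum over 4 H4 genes went from 551 ± 96 to 85.7 ± 20.6, from 430 ± 156 to 37.3 ± 4.77 and from 530 ± 2.84 to 103 ± 80.6. Reads moving only among the genes summed would leave these sums alone. Yet the lower of the H2A and H1 ratios in PC9, lowest dormant over highest DMSO library, was 16.9. The sums hold only genes found by a histone symbol, and 12 histone genes of the lists were not found. Reads moving to or from genes outside the sums are therefore not excluded. For H2A the ratio was 43.1 in HCC827 and 6.73 in HCC4006 (5.45 and 3.94 without HIST3H2A). For H1 it was 2.34 and 0.924, so that H1 in HCC4006 is not shown to rise. Weaker selection of polyadenylated RNA in dormant libraries could raise histone transcripts without a tail, and would raise other RNA without one. Whether the histone transcripts counted here had a tail was not measured. The median difference of 187 small RNA genes was 0 in PC9 (95% bootstrap interval -0.06 to 0), -0.26 in HCC827 (-0.4 to -0.16) and 0.67 in HCC4006 (0.4 to 0.85), but 96 of these genes had a mean under 1 FPKM, too near the floor for this to decide. Over genes with a mean of at least 10 FPKM in the other 2 lines, the median was -0.73 in HCC827 (16 genes, -1.11 to -0.46), which argues against weaker selection there. The DMSO side of that median includes the doubted library, and no value without it was computed. Mitochondrial tRNA went the other way in HCC827, from 0.86% and 1.47% of summed FPKM in DMSO to 2.66% and 2.53% in dormant libraries. Mitochondrially encoded genes were higher there too as a list. In PC9 the median of the small RNA genes was 0.1 (17 genes, -0.29 to 0.54), with a median DMSO level of 0.89 FPKM. In HCC4006 it was 2.68 (3 genes, 0 to 4.6), being 0 for the first dormant library and 6.01 for the second. Both of these libraries had similar H2A sums (59.3 and 55.3). Without HIST3H2A they differed, the sum being 40.2 ± 21.4 in dormant HCC4006 and 6.06 ± 0.449 in DMSO. Weaker selection alone would raise H4 along with H2A, whereas the H4 sums fell in each line. This argues against weaker selection as the only change, though a part played by it remains open in PC9 and HCC4006 and is not excluded in HCC827. A change in histone transcripts with dormancy remains open too, and duration and dish size are confounded with dormancy.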

How the results depend on the processing

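The fit without both doubted libraries, the trend removal, the fits on either column and the grouping of splits by mixing were chosen only after the results were seen, and the other alternatives were planned. Directions held more often than counts. Of 193 called gene results, 2 lost their call with robust variance estimation, 27 with a pseudocount of 0.1, 36 with array quality weights, 42 with no filter, 44 with the replicate block and 0 to 65 with a library left out, as did 47 of the 62 tested with each line alone and 129 of the 131 tested with line means. Of 62 list calls, 60 were lost with an estimated correlation and 21 with fry, which added 7. ZEB1 in HCC4006 was the only called result to change direction under any alternative (-0.05 under trend removal, where the mean of ZEB1 also became -0.08). With each library left out in turn, 93 of 131 named genes and 12 of 17 lists kept their call in the mean in every case. A gene's spread is estimated once over all 6 groups. Leaving out a library of 1 line therefore moves the totals of the other lines through that spread and its degrees of freedom, while their own differences stay the same. Beyond that, the cause was not tested for any total that moved. Without both doubted libraries, which leaves 2 groups with a lone library assumed to vary like the others, totals were 3191 in PC9, 2599 in HCC827, 2734 in HCC4006, 6299 in the mean, 1311 between lines, 409 higher and 216 lower in all lines. With array quality weights they were 4487, 1620 and 24 for the lines and 465 between lines, with 4 genes higher in all lines (CCDC80, CTGF, NPPB and UBD) and 1 lower (PRSS3), named after their values were seen, as are the genes below. With each line fitted alone, PC9 had 2682, and limma called 0 in HCC827 and 0 in HCC4006, hence 0 higher and 0 lower in all lines, with 3633 and 916 genes at an unadjusted p under 0.05. Replicate differences of DMSO and dormant libraries correlated across genes at 0.09 in PC9, 0.04 in HCC827 and 0.17 in HCC4006. These values give little sign that libraries pair by replicate number, but do not exclude it. The replicate block gave 123, 162 and 486 in these lines, with 2 between lines (COL1A2 and TNFAIP6), 6 higher in all lines and 1 lower. With line means as replicates 2 genes were called in the mean, NPPB and PSG5. With an estimated correlation 1 list was called, mitosis. A pseudocount of 0.1 gave 246 in PC9, 574 in HCC4006 and 60 between lines. With no filter HCC4006 had 446, the mean 1498, and 6 genes were lower in all lines. Requiring 5 FPKM gave 544 in HCC4006. Median of ratios scaling gave 630 in PC9, 587 in HCC4006 and 32 lower in all lines, quantile normalization 678 in PC9 and 47 lower in all lines, equal column sums 6 lower in all lines, and trend removal 53 higher and 69 lower in all lines. Leaving out each library in turn gave 95 to 1638 in PC9, 84 to 2974 in HCC827, 128 to 8607 in HCC4006, 1025 to 7390 in the mean, 65 to 8050 between lines, 5 to 218 higher and 1 to 133 lower in all lines. The 5 were CYP1A1, FILIP1L, GABARAPL1, NPPB and PSG5 (without the second HCC827 dormant library), and the 1 was HMGA1 without any 1 of the 4 PC9 libraries and another gene without either HCC827 dormant library. The highest values came without the first HCC4006 dormant library, except the 218, which came without the second.

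The other changes of direction concerned results that were not called. The direction of a list is that given by its test, which can differ in sign from the value given. As mean log2 differences less that of all genes, the replication-dependent histones, at 0.00, gave -0.15 with a pseudocount of 0.1, -0.02 with 0.5, -0.07 with 5 FPKM, -0.01 with equal sums, 0.00 with array weights and with line means, and -0.10 to 0.09 with a library left out. Secreted factors of senescent cells gave 0.34 with no filter. Requiring 5 FPKM gave -0.09 for the Hippo list, -0.29 for p53 targets, -0.14 for receptor kinases and -0.37 for alveolar genes, and trend removal gave 0.02, -0.18 and -0.08 for the last 3. Basal genes gave 0.16 with line means and with fry, hypoxia genes 0.06 with fry, and cholesterol genes -0.15 to 0.26 with a library left out. YAP1 in the mean gave -0.05 without both doubted libraries and -0.18 to 0.93 with a library left out.

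Of 100 splits of the libraries within lines, the real one included, 1 gave as many genes called in the mean. The real value was 2268 and the highest other 601. This excludes chance only if the libraries of a line were interchangeable. Since the plates of a group may share a culture, the rank shows that duplicates are alike and not what sets the groups apart. For the number of lists chance cannot be excluded by this count, since 6 of 100 splits gave as many as the real 17, the highest other being 19. However, these other splits all kept or mirrored the real grouping in at least 2 lines and so carry much of the contrast, and the 30 splits mixed in all 3 lines gave 0 to 4 lists. No depth in reads is known, so how far counting error limits genes at low FPKM was not assessed.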

Other observations

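All fits without both doubted libraries given here were chosen only after the results were seen, whereas the lists were fixed beforehand.

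Further gene lists held single genes that changed in the mean over lines, and none of them was called as a list there by camera with all 12 libraries and the usual filter. Other planned tests did call some. Without a filter on low values these were the lists of amino acid and ER stress (adjusted p = 0.0114), persister (adjusted p = 0.0141) and motile cilia genes (adjusted p = 0.00747). The 40839 genes of that fit had a median difference of 0.03, which can favour upward calls of expressed lists. With fry, a rotation test of each list by itself, they were the lists of immediate early (adjusted p = 0.0145), receptor kinase (adjusted p = 0.0334), persister (adjusted p = 0.0264), cilia (adjusted p = 0.00446) and fibroblast and endothelial genes (adjusted p = 0.000267). Fry tests against a difference of 0, whereas all tested genes had a median of 0.22, which favours upward calls. The receptor kinase list stood at 0.00 relative to all genes. Without the first HCC827 DMSO library the ER stress list was called (adjusted p = 0.0134). Of the genes named below, FOS, VLDLR, ERBB2, ERBB3, EPHA2, KDM6A, SC5D, SQLE, KRT16, HOPX, ITGB2 and ESAM lost their call in the mean in at least 1 case of a library left out, in up to 10 of 12 cases for ESAM. DUSP1, a phosphatase that inactivates MAP kinases, rose by 3.27 ± 0.29 (adjusted p = 0.000212) and was called in each line. It belongs to 13 immediate early and handling stress genes, of which ATF3 (1.53 ± 0.24) rose too and EGR1 (-0.79 ± 0.17) and FOS (-0.55 ± 0.13) fell (3 and 2 adjusted over the list alone; list adjusted p = 0.501; 6 rose and 2 fell without both doubted libraries). Of 24 genes of the amino acid and ER stress response, DNAJB9 (2.61 ± 0.37), HERPUD1 (2.31 ± 0.42), ATF3 and VLDLR (1.03 ± 0.25) rose by both adjustments (list adjusted p = 0.138; 12 rose without both doubted libraries). Of 20 hypoxia response genes, EGLN3 (2.5 ± 0.32), ADM (2.15 ± 0.4), LOX (2.09 ± 0.31) and MXI1 rose and ANGPTL4 (-1.61 ± 0.3) and CA9 fell, by both adjustments (list adjusted p = 0.603; 6 rose and 6 fell without both doubted libraries). The hypoxia list's median of 0.13 and mean of 0.25 were positive while camera ranked it below other genes. Its members EGLN3 (adjusted p = 0.0419) and LOX (adjusted p = 0.00965) were called different between lines by the F test. Of 18 receptor tyrosine kinases, 7 rose and 1 fell by both adjustments (list adjusted p = 0.501; 8 and 4 without both doubted libraries), DDR1 by 1.51 ± 0.24, ERBB2 by 1.43 ± 0.31 and ERBB3 by 1.16 ± 0.24, while EPHA2 changed by -1.29 ± 0.36. Of 22 persister and detoxification genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone; list adjusted p = 0.274; 12 and 3 without both doubted libraries), including the aldehyde dehydrogenase ALDH1A3 (1.92 ± 0.27), the histone demethylases KDM5B (1.48 ± 0.26) and KDM6A (1.04 ± 0.25), and the aldo-keto reductase AKR1B10 (-1.49 ± 0.22). Of 23 cholesterol synthesis genes, SC5D (1.49 ± 0.31) and SQLE (1.0 ± 0.25) were among those that rose by both adjustments (list adjusted p = 0.533; 10 rose and 3 fell without both doubted libraries). In PC9 the cholesterol list was called upwards (adjusted p = 5.73e-05; adjusted p = 0.447 with an estimated correlation). Camera also called the ER stress (adjusted p = 0.00407), persister and cilia lists (both adjusted p = 0.0461) in PC9. In HCC827 it called the receptor kinase (adjusted p = 0.0291) and alveolar lists (adjusted p = 0.0378). These calls were lost with an estimated correlation, and all but that of ER stress in at least 2 of 12 cases of a library left out. Of 11 tested genes of the list of replication-dependent histones, 5 rose and 3 fell by both adjustments (list adjusted p = 0.913). They ranged from HIST1H1C at 2.82 ± 0.43 and HIST1H4H at 1.95 ± 0.27 to HIST1H1E at -1.58 ± 0.24 and HIST1H4C at -3.19 ± 0.37. Whether their transcripts had a poly(A) tail was not measured.

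Markers of other cell types held called genes of both directions in 3 of 6 lists. Of 12 basal and squamous cell genes, 4 rose and 4 fell by both adjustments (list adjusted p = 0.576; 4 and 5 without both doubted libraries), the keratins KRT17 (3.68 ± 0.59) and KRT16 (2.51 ± 0.6) and TRIM29 (1.91 ± 0.4) rising and KRT6A falling (-1.89 ± 0.4), with a mean of 0.35 while camera ranked the list below other genes. Of 16 alveolar and club secretory cell genes, 5 rose and 3 fell by both adjustments (list adjusted p = 0.668; 8 and 3 without both doubted libraries), among them HOPX (1.15 ± 0.31), AQP4 (0.84 ± 0.16) and CEACAM6 (-2.48 ± 0.27). SCGB3A1 went from 6.06 ± 0.75 FPKM to being listed at 0 in each dormant library of HCC4006 and was listed at 0 in all libraries of the other lines. Of 5 neuroendocrine genes, SCG5 rose (1.71 ± 0.26) by both adjustments (list adjusted p = 0.605; 2 rose and 1 fell without both doubted libraries). Of 8 motile cilia genes, TPPP3 rose (1.61 ± 0.17; 2 rose adjusted over the list alone; list adjusted p = 0.138; 3 rose without both doubted libraries). Of 6 haematopoietic cell genes, the integrin ITGB2 rose (0.87 ± 0.21) by both adjustments (list adjusted p = 0.603; 1 rose and 3 fell without both doubted libraries). Of 5 fibroblast and endothelial cell genes, COL1A2 (2.5 ± 0.21) and COL1A1 (1.32 ± 0.2) rose and ESAM fell (-0.62 ± 0.18) by both adjustments (list adjusted p = 0.16; 3 and 1 without both doubted libraries). In HCC4006 that list was called upwards (adjusted p = 0.00378; adjusted p = 0.225 with an estimated correlation), a call lost in 1 of the 12 cases of a library left out. Of the 21 genes of the full list, 12 also belong to another list. TPPP3 of the cilia list was called different between lines by the F test (adjusted p = 0.00139), so its mean does not describe each line.

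Both columns of each library gave near-identical values, with a Pearson r across genes of 0.993 or 0.994 in every library.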
